A study of Mus musculus with 5 samples.

How the data were processed

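Hearts from 5 wild-type mouse embryos at E12.5 were measured, per the labels, on Affymetrix mouse 430A arrays, which carry short oligonucleotide probe sets for known transcripts. RNA was prepared from single tissue isolates with Trizol and a spin column, and a small amount was amplified with the WT-Ovation Pico kit and labelled with biotin, per the labels' protocols. The labels give the strain as 129P2/OlaHsd backcrossed to C57BL/6 for 2 generations. The hearts are separate samples of 1 group. Whether they came from 1 litter or several is not given in the sources used here. The variance and list spread tests measure the spread between these hearts, and Fisher's tests compare counts of genes.

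The deposited table holds 1 linear intensity per probe set and array. The authors used GCOS, per the submitters' processing notes. Its version, the summary algorithm and its settings are not given in the sources used here. From the values, the deposited intensities had been scaled so that the 2% trimmed mean agreed between arrays at 150.1. Detection calls were not used here. A low amount of input RNA and amplification from it can raise noise for weak transcripts, and a shared scale removes any difference in total signal between hearts.

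The table holds 22690 probe sets, of which 20393 have 1 gene symbol in the platform annotation, 691 have several and 1606 are not listed in it. Affymetrix controls made up 64 of the probe sets. Of those with 1 symbol, 20364 matched the GRCm38.p6 gene table by Entrez number. That table gave names and neighbours of genes only. After control probe sets were left out, 20380 probe sets of 12393 genes were used. A gene was represented by its probe set with the highest mean over hearts, so its values rest on a single probe set. Levels of named genes were not compared with each other. Detection, and the tests that match genes on mean level, did set probe sets of different genes against each other. They thus also depend on how strongly a probe set responds.

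Intensities were scaled to a common trimmed mean, which changed no call, and analysed as log2(intensity + 16). The offset compresses differences of weak genes, so a fold change on this scale understates them. Calculations used R 4.3.3 and limma 3.58.1. The background of an array was the 95th percentile of 61 measured genes of tissues unrelated to heart, such as lens, retina, testis and pancreas. Detected means above this level in all 5 hearts.

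Before the data were examined, 22 gene lists were fixed. They covered cardiac transcription factors, sarcomere, calcium handling and ion channels, atrial markers, ventricular and trabecular markers, cushion and valve mesenchyme, endocardium and endothelium, epicardium, smooth muscle and neural crest, and signalling. Further lists covered erythroid cells, macrophages and leukocytes, cell cycle, glycolysis, fatty acid oxidation, hypoxia, immediate early and heat shock genes, sex-linked genes, liver, lung and foregut epithelium, skeletal muscle, and neurons. The lists overlap in part. Each list's detected share was compared with all other genes outside the off-tissue list by a two-sided Fisher's exact test, adjusted over the lists by Benjamini-Hochberg.

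Genes that vary between hearts were called by an F test built on limma's prior variance, named limma's variance test below. Each gene's variance (4 degrees of freedom) was tested against a robust prior variance that follows the mean level (12.06 degrees of freedom), upper tail. Adjustment was by Benjamini-Hochberg over genes, with a threshold of 0.05. Each list's median SD was set against 10000 random lists matched on mean level in 20 bins, two-sided, which describes these arrays because genes of a list are not independent. With 1 group there was no contrast to test.

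Genes were named by a rule fixed before the data were examined. It took the first 3 measured genes of each list in written order, all sex-linked genes, and up to 20 genes past the variance test whose mean was above background. It also took the 3 genes of largest SD in each list past the spread test. Members of heart lists above background in no heart could be named in counts of 5 or fewer. Other names were chosen after their values were seen.

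The alternatives were the deposited values unscaled, quantile normalization, offsets of 1 and 64, the mean of a gene's probe sets, probe sets of type _x_at or _s_at left out, each heart left out, and background at the 90th or 99th percentile. Further alternatives were detection in at least 3 hearts, dim genes left out, and a variance prior without robust estimation or without trend. Each probe set tested on its own and a background list without Prm1 and Pomc were added after the data were examined, as was a second list of 24 red cell genes outside the 22 lists, of which 20 were measured. The tests were first tried on simulated data and on random lists. Simulated values followed the variance test's own fitted model with independent genes, so they do not give its error rate in the measured data. In them 1 false call was made among the unshifted of 12393 genes. A list given 2.5 times the spread was called with 0 of 21 others. Of 440 random lists drawn on the measured detection calls, 1 was called above or below background.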

Results

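Gene expression was measured in whole hearts dissected from 5 wild-type mouse embryos at E12.5, a stage of midgestation at which the chambers are forming, the endocardial cushions are being remodelled into valves and the epicardium covers the surface. RNA from each heart was hybridised to its own Affymetrix mouse 430A array. The hearts carry the replicate numbers 6 to 10 in the labels and are named by them here. They form 1 group with no second condition in the labels, which do not give the sex of the embryos. The design thus asks which genes and cell types gave signal in these hearts and how alike the hearts were. All levels are log2 of the intensity plus 16, given as mean ± SD over 5 hearts. A gene is called detected where it exceeded the array's background in all 5 hearts. A gene that was not detected may still be expressed, since its level rests on 1 probe set. Genes outside the naming rule, such as those detected in some hearts only, were chosen after their values were seen. The number of arrays limits the precision of every value.

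The embryonic heart gave signal above background for 6608 of 12393 genes in all 5 hearts, or 53.3%. A further 2086 genes were above background in some hearts only, and 3699 in none. Of 61 genes of unrelated tissues that set the background, 1 exceeded it in all hearts, the sperm protamine gene Prm1. None of 27 bacterial control probe sets exceeded it in any heart. The deposited intensities had a trimmed mean of 150.1 on every array and array medians between 27.1 and 30.4. The number of genes above background per array was 7787 in heart 6, 7415 in heart 7, 7398 in heart 8, 7300 in heart 9 and 8093 in heart 10.

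The hearts resembled each other closely across genes. Pearson's r over 12393 genes lay between 0.965 and 0.983 for the 10 pairs of hearts, with a median of 0.976, and Spearman's rho between 0.935 and 0.957. These are correlations across genes, which are not independent replicates. The median SD between hearts was 0.26 over all genes and 0.24 over detected genes, for which the median coefficient of variation of the intensity was 19.2%. No pair of arrays held identical values. Heart 7 had the lowest median r with the other hearts, 0.969, against 0.976 to 0.980 for the rest. Its ratio of 3' to 5' Gapdh control signal was 5.69, against at most 3.55 in the others, while its actin ratio of 4.27 lay below the 4.48 of heart 8.

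Most listed genes of the contractile apparatus and of cardiac transcription were detected. Of 27 measured sarcomere genes, 25 were detected (92.6%), among them cardiac troponin T, Tnnt2, at 13.00 ± 0.15, the alpha myosin heavy chain Myh6 at 11.97 ± 0.14 and the beta chain Myh7 at 12.69 ± 0.21 (n = 5 each). The M-band gene Myom2 was above background in no heart and the leiomodin gene Lmod2 in some. Of 24 cardiac transcription factors, 20 were detected (83.3%), including Nkx2-5 at 5.64 ± 0.28, Gata4 at 8.47 ± 0.20 and Tbx5 at 8.14 ± 0.45. Hand1 was above background in no heart, and Tbx2, Irx5 and Prox1 in some. Both lists were detected more often than the remaining genes, of which 53.5% were detected. The odds ratio was 10.9 for the sarcomere (95% confidence interval 2.71 to 94.7, adjusted p = 0.000408) and 4.34 for the transcription factors (1.45 to 17.5, adjusted p = 0.0126), by two-sided Fisher's exact tests adjusted over 22 lists. The transcription factor call was lost under 3 other settings. It had an adjusted p of 0.193 with the probe sets of a gene averaged, 0.565 with a stricter background and 0.0621 when 3 hearts sufficed.

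Genes of chamber identity and of calcium handling were detected in part. Among 13 atrial markers, 10 were detected, including the natriuretic peptide gene Nppa at 11.93 ± 0.16 and the atrial light chain Myl4 at 12.92 ± 0.14. Sarcolipin, Sln, a regulator of the sarcoplasmic calcium pump, had a level of 5.68 ± 0.19 and exceeded background in 4 hearts. Among 12 ventricular and trabecular markers, 8 were detected, with the ventricular light chain Myl2 at 13.19 ± 0.17 and the ventricular transcription factor Irx4 at 6.17 ± 0.38, whereas Bmp10 and Slit3 exceeded background in no heart. Of 21 genes of calcium handling and ion channels, 14 were detected. The calcium pump gene Atp2a2 had a level of 11.78 ± 0.13 and the gap junction gene Gja1 of 11.37 ± 0.13, while Cacna1g, Kcnj2, Kcnj5, Kcnd2 and Kcnd3 exceeded background in no heart. By Fisher's exact test none of these lists passed (adjusted p = 0.209, 0.553 and 0.435 in the order given). The atrial list passed (adjusted p = 0.0477) when 3 hearts sufficed.

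Energy metabolism and proliferation gave signal in nearly all their listed genes. All 16 measured glycolysis genes were detected, with the glucose transporter Slc2a1 at 12.43 ± 0.17, the hexokinase Hk1 at 7.75 ± 0.28 and the muscle phosphofructokinase Pfkm at 8.10 ± 0.25. Of 16 genes of fatty acid oxidation, 15 were detected, including Cpt1a, which controls fatty acid entry into mitochondria, at 8.06 ± 0.15 and the dehydrogenase Acadm at 7.05 ± 0.48. Ppara, a transcriptional regulator of this pathway, exceeded background in no heart (4.23 ± 0.14). Of 22 cell cycle genes, 20 were detected, with the proliferation marker Mki67 at 10.65 ± 0.13, the topoisomerase Top2a at 10.14 ± 0.11 and the kinase Cdk1 at 8.89 ± 0.13, while Aurkb and Tyms exceeded background in some hearts. Fisher's exact test gave an adjusted p of 0.000553 for glycolysis, with an odds ratio of at least 3.35 at the lower 95% bound. The odds ratio was 13.0 (2.00 to 547) for fatty acid oxidation, with adjusted p = 0.00339, and 8.69 (2.11 to 76.6) for the cell cycle, with adjusted p = 0.00244. Of 13 hypoxia response genes, 10 were detected, which did not pass (adjusted p = 0.209) except when 3 hearts sufficed (adjusted p = 0.0477). Pdk1 had a level of 9.17 ± 0.42 and Bnip3 of 9.82 ± 0.27, and Vegfa (5.26 ± 0.37) exceeded background in 4 hearts. Among immediate early and heat shock genes, which respond to handling and stress, 7 of 15 were detected (adjusted p = 0.680), with Egr1 at 8.73 ± 0.22 and Hspa1b at 6.78 ± 0.53, and Fos (5.15 ± 0.46) exceeded background in 2 hearts.

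Markers of the cushions, epicardium, endothelium, smooth muscle and leukocytes, and signalling genes, were detected in part, and none of these lists passed the test. Of 24 genes of cushion and valve mesenchyme and matrix, 18 were detected, including the proteoglycan Vcan at 10.22 ± 0.17, the matrix protein gene Postn at 9.11 ± 0.31 and the transcription factor Sox9 at 6.55 ± 0.30, while Msx2 and Snai1 exceeded background in no heart. Of 10 epicardial genes, 8 were detected, with Wt1 at 7.20 ± 0.15 and Tbx18 at 7.16 ± 0.24, and Tcf21 exceeded background in 4 hearts. Of 24 endocardial and endothelial genes, 14 were detected, including the VEGF receptor Kdr at 6.46 ± 0.31, Tek at 10.44 ± 0.39 and Icam2 at 8.28 ± 0.06. A further 8 exceeded background in some hearts, and Cdh5 and Sox18 in none. Pecam1 was among the 8, above background in 2 hearts. Of 13 smooth muscle and neural crest genes, 6 were detected, with Acta2 at 11.16 ± 0.10 and Tagln at 9.76 ± 0.06. Sema3c exceeded background in 4 hearts, whereas the neural crest genes Sox10, Foxd3, Pax3 and Wnt1 exceeded background in no heart. Of 16 macrophage and leukocyte genes, 10 were detected, including the growth factor receptor Csf1r at 8.35 ± 0.57 and Cd68 at 5.39 ± 0.05. Cd68 lay only just above background, with 5.36 against 5.33 in heart 9. The pan-leukocyte gene Ptprc exceeded background in 1 heart (4.76 ± 0.27). Of 33 signalling ligands and receptors, 20 were detected, including Bmp4 at 6.42 ± 0.22 and Notch1 at 7.04 ± 0.29, while Erbb2 exceeded background in 2 hearts (5.22 ± 0.37). The adjusted p by Fisher's exact test was 0.111 for the cushion list, 0.216 for the epicardium, 0.719 for endothelium, 0.782 for smooth muscle and neural crest, 0.680 for macrophages and 0.629 for signalling. The cushion list passed without heart 9 (21 of 24 genes, adjusted p = 0.00364), without probe sets prone to cross-hybridise (0.0356) and at a lower background (0.0199). When 3 hearts sufficed, the cushion list (adjusted p = 0.0278) and the epicardial list (0.0275) passed.

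Red blood cell transcripts were present in every heart. Of 14 measured erythroid genes, 9 were detected (adjusted p = 0.680 by Fisher's exact test), among them the embryonic globin genes Hba-x at 12.44 ± 0.41, Hbb-bh1 at 12.00 ± 0.34 and Hbb-y at 13.10 ± 0.21. Hba-a1 and Rhag exceeded background in no heart by the probe sets used. Probe sets with several gene symbols were left out, so this does not show that these genes were not expressed. Few listed genes of liver and of lung and foregut epithelium were detected. Of 14 liver genes, 1 was detected, the thyroxine carrier gene Ttr at 5.95 ± 0.24, and the abundant liver products Afp and Alb exceeded background in no heart. Apoa2 exceeded background in 4 hearts, with 4.50 in heart 6 and 5.99 to 6.52 in the others, and Ahsg in 1. Of 10 lung and foregut epithelial genes, 1 was detected, Grhl2, while Nkx2-1 exceeded background in 1 heart and Sftpc and Foxa2 in none. Both lists were detected less often than the remaining genes. The odds ratio was 0.0665 (95% confidence interval 0.00157 to 0.443) for liver, with adjusted p = 0.00290, and 0.0962 (0.00220 to 0.694) for lung and foregut, with adjusted p = 0.0244, by Fisher's exact test. Of 14 skeletal muscle genes, 4 were detected, Tnnt3 at 6.39 ± 0.23, Tnni2 at 9.01 ± 0.31, Ckm at 5.91 ± 0.31 and Mylpf at 6.89 ± 0.21. The myogenic regulators Myod1, Myog and Myf5 exceeded background in no heart. Of 11 neuronal genes, 3 were detected, Stmn2, Gap43 and Nefl, while Tubb3 exceeded background in 4 hearts and Elavl4 in none. The adjusted p by Fisher's exact test was 0.209 for skeletal muscle and 0.216 for neurons, and skeletal muscle passed as less often detected when 3 hearts sufficed (adjusted p = 0.0477).

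**Figure D1:**
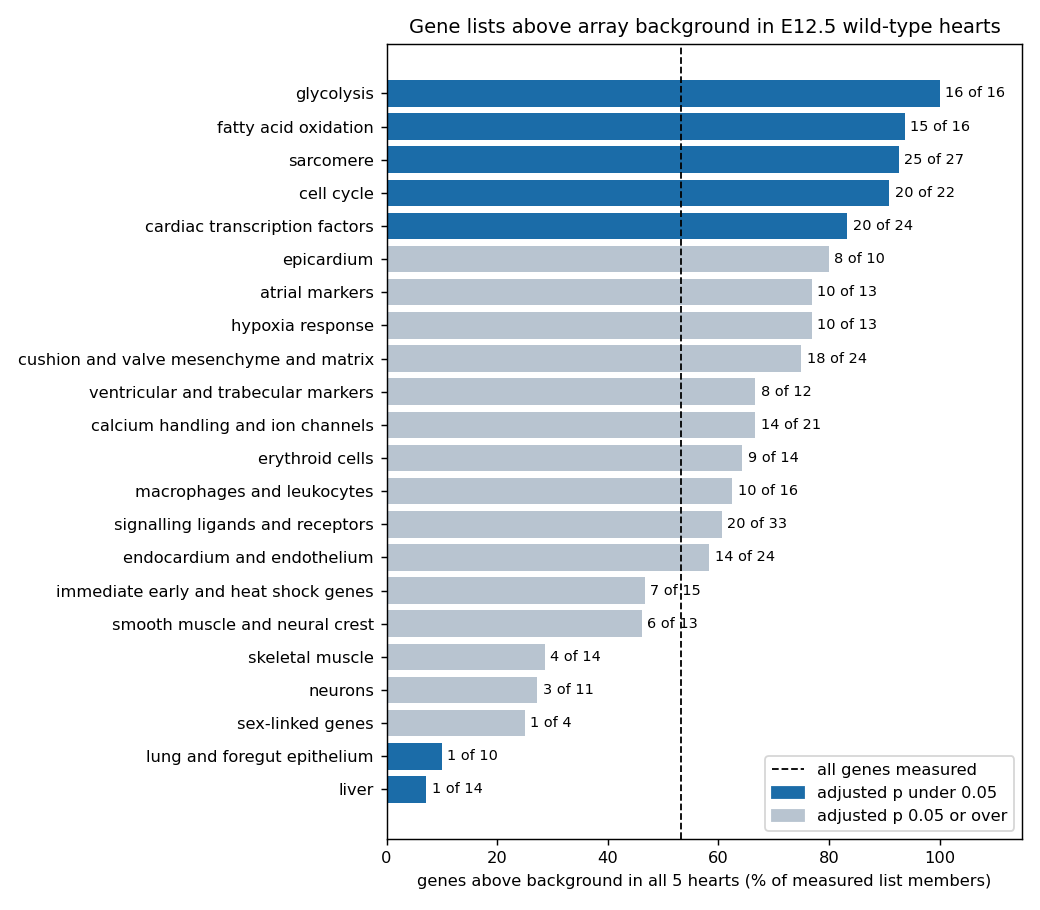
Percent of each list's measured genes above background in all 5 hearts, with the counts beside the bars. Blue bars passed the two-sided Fisher's exact test (adjusted p under 0.05), grey bars did not, and the dashed line marks the 53.3% of all genes; glycolysis reaches 100% and liver 7.14%.

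The largest differences between hearts lay in sex-linked genes. Xist, the non-coding RNA of the inactive X chromosome, had levels of 10.46, 9.83 and 10.16 in hearts 6, 7 and 8, and of 6.77 and 5.01 in hearts 9 and 10. Eif2s3y, a Y-linked translation factor gene, showed the opposite pattern, with 4.17, 4.03 and 4.07 in hearts 6, 7 and 8 and 9.15 and 9.64 in hearts 9 and 10. Kdm5d, a Y-linked histone demethylase gene, had 4.56, 4.46 and 4.53 in hearts 6, 7 and 8 and 5.65 and 5.68 in hearts 9 and 10. Uty, also Y-linked, exceeded background in no heart. High Xist with Eif2s3y below background marks hearts 6, 7 and 8 as female. Eif2s3y and Kdm5d above background mark hearts 9 and 10 as male. No test used this split. Across all genes, limma's variance test called 5 genes more variable than genes of similar level, with 551 at an unadjusted p under 0.05 where 619.7 were expected. The prior was estimated from these same genes, so a count near the expected one does not measure how much the hearts vary. Eif2s3y (SD 2.91, adjusted p = 3.40e-05) and Xist (SD 2.43, adjusted p = 5.07e-05) led the calls. The remaining calls were Ctr9, Lancl2 and B3galt6. Ctr9, which encodes a subunit of a transcription elongation complex, had 10.53 in heart 7 and 5.63 to 6.59 in the others (adjusted p = 0.000719). Lancl2 had 6.22 and 5.72 in hearts 6 and 7 and 8.84 to 9.01 in hearts 8, 9 and 10 (adjusted p = 0.00432). B3galt6, a glycosyltransferase gene, had 5.01 and 5.25 in hearts 8 and 10 and 7.47 to 7.73 in the others (adjusted p = 0.0280). Another Ctr9 probe set differed by 0.06 between heart 7 and the others, and without probe sets of type _x_at or _s_at Ctr9 was not called (adjusted p = 0.976). Ctr9, Lancl2 and B3galt6 were also not called without a robust prior (adjusted p = 0.0857, 0.164 and 0.875) or without its trend (0.0623, 0.208 and 0.495), and B3galt6 not at an offset of 64 (0.109). With the probe sets of a gene averaged, 1 gene was called, Eif2s3y, and Xist had an adjusted p of 0.0818. Without heart 7, 9 genes were called and Ctr9 was not (adjusted p = 0.970), and without heart 8, 3 genes were called and Lancl2 was not (0.0706). B3galt6 was not called without heart 6, 8, 9 or 10 (adjusted p = 0.0772, 0.551, 0.107 and 0.231).

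**Figure D2:**
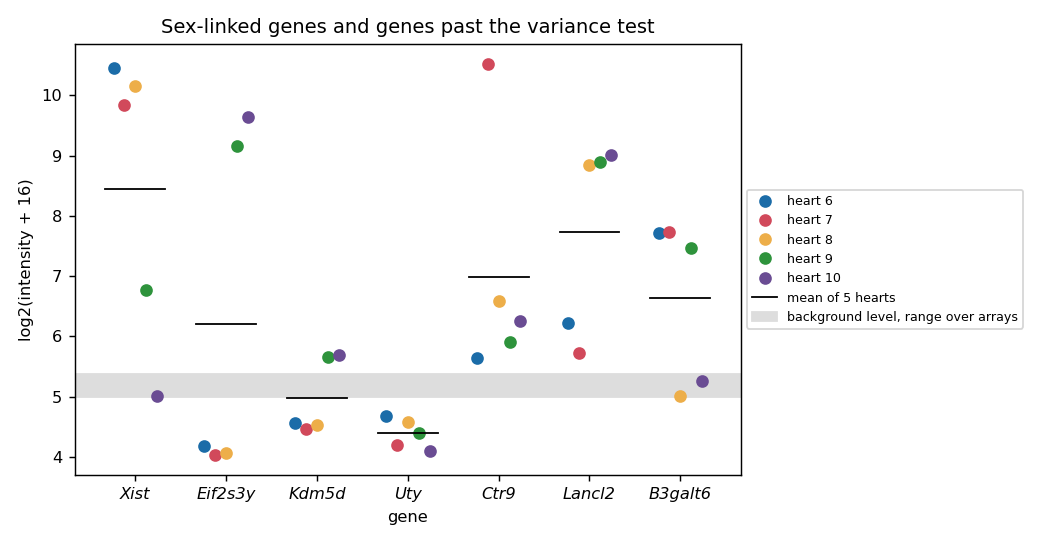
Log2 level of sex-linked genes and of genes called by limma's variance test, with 1 point per heart on the log2(intensity + 16) axis, a line at the mean and a grey band for the background levels of the arrays. Eif2s3y lies at 9.15 and 9.64 in hearts 9 and 10 and at 4.03 to 4.17 in the others, and Ctr9 stands apart in heart 7 alone.

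Red blood cell genes also differed between hearts as a group. The median SD of 14 erythroid genes was 0.413, against a median of 0.230 for 10000 random lists of similar level (95% range 0.168 to 0.302), a ratio of 1.80 (adjusted p = 0.00220, two-sided resampling). No random list reached this spread, so the unadjusted p was the smallest that they can give. Alas2, the first enzyme of erythroid haem synthesis, had 11.34 in heart 7 and 8.96 to 10.50 in the others. Slc4a1, the red cell anion exchanger, had 11.00 in heart 7 and 9.48 to 9.68 in the others, and Klf1, an erythroid transcription factor, had 7.04 in heart 7 and 5.40 to 6.30 in the others. No erythroid gene passed limma's variance test over all genes (Alas2 adjusted p = 0.112), and 4 passed when adjusted over the list alone (Alas2, Slc4a1, Klf1 and Hba-x). Of the 9 detected genes, 7 had their highest level in heart 7. Without heart 7 the ratio was 1.51 (adjusted p = 0.0425). Heart 7 also had the highest Gapdh 3' to 5' ratio, but not the highest actin ratio, both given above.

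Of 4 measured sex-linked genes, 1 was detected, Xist (adjusted p = 0.503 by Fisher's exact test). The list had a spread ratio of 5.44 (adjusted p = 0.00220), with 2 genes past the variance test over all genes and 3 adjusted over the list alone (Xist, Eif2s3y and Kdm5d). Genes of calcium handling and ion channels varied less than random lists. Their median SD was 0.161 against 0.253 (ratio 0.635, adjusted p = 0.00733), although Ryr2, the sarcoplasmic calcium release channel gene, had 6.70 in heart 7 and 7.45 to 7.96 in the others, and the calcium channel gene Cacna1h had an SD of 0.41. This call was lost without heart 6, 8, 9 or 10 (adjusted p = 0.147, 0.258, 0.0909 and 0.157) and at offsets of 1 and 64 (adjusted p = 0.135 and 0.513). It was also lost with the probe sets of a gene averaged (adjusted p = 0.133) and without dim genes (0.114). The other 19 lists had ratios between 0.835 and 1.31 and did not pass, the lowest adjusted p being 0.406. Among them, only the liver list had a gene past the variance test adjusted over the list alone (1 gene, Apoa2), and none had a gene past it over all genes. In simulated data for the variance test, a shift of 2 log2 units in 1 heart of 5 was called for 16 of 100 genes and a shift of 4 for 100 of 100. Shifts of 2 log2 units or less in 1 heart were thus mostly not detectable. Shifts between 2 and 4, and differences shared by several hearts, were not simulated.

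**Figure D3:**
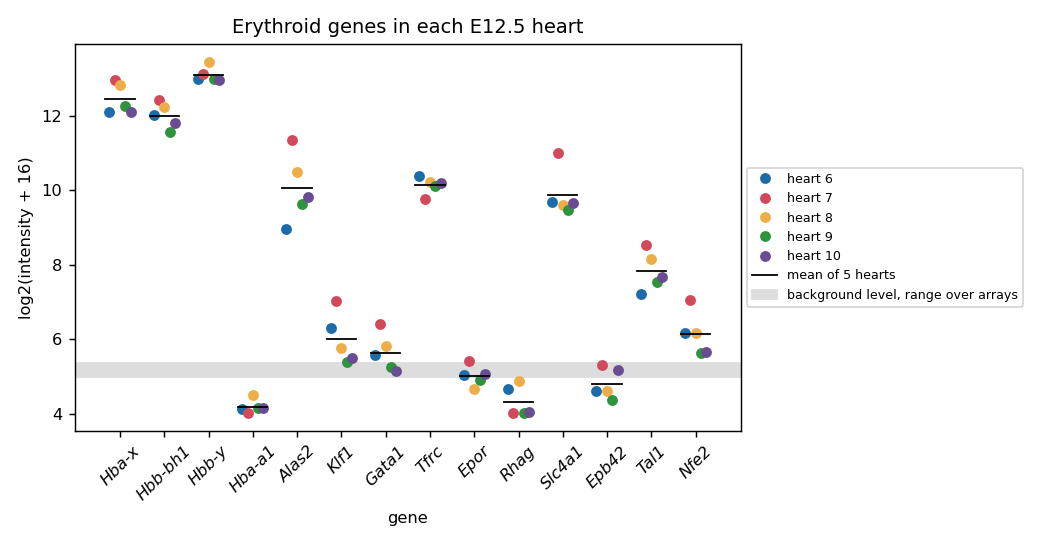
Log2 level of erythroid genes in each of the 5 hearts on the log2(intensity + 16) axis, with a line at the mean and a grey band for the background levels of the arrays. Alas2, Slc4a1 and Klf1 have their highest values in heart 7, at 11.34, 11.00 and 7.04.

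**Figure D4:**
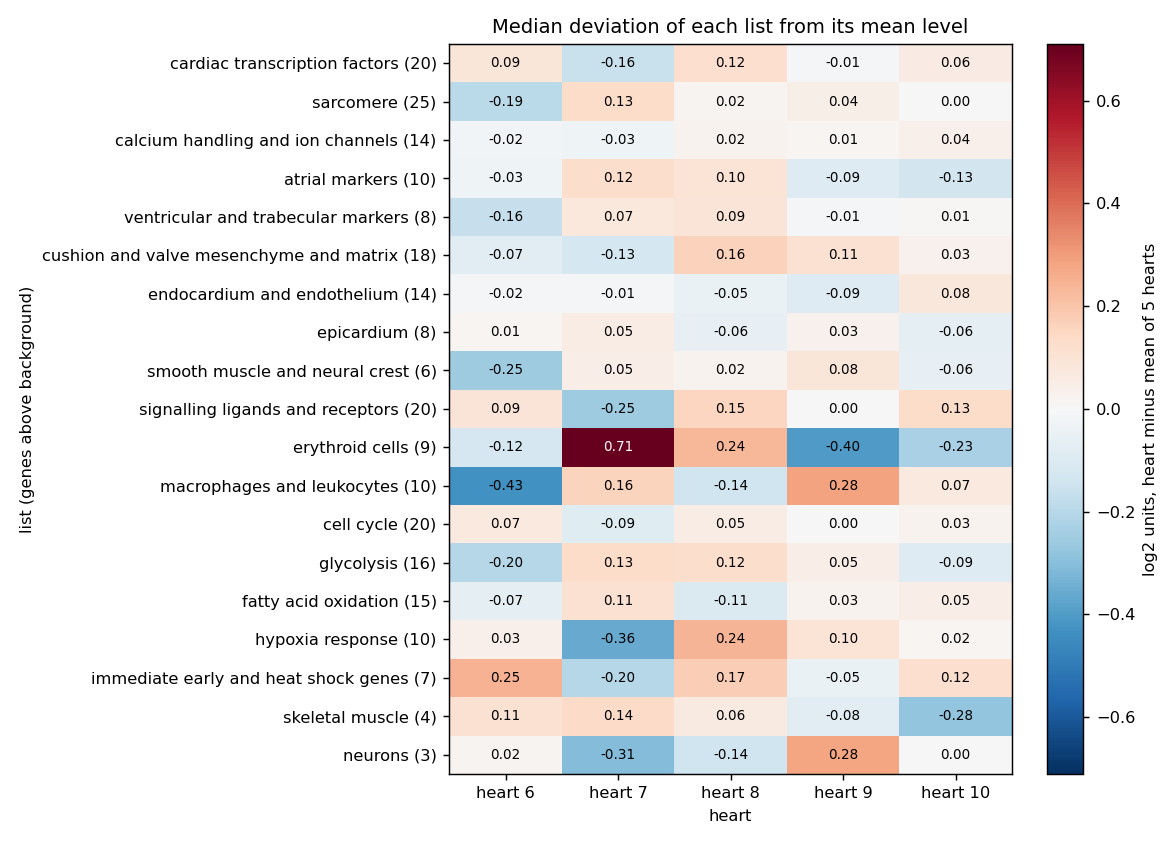
Median deviation of each list's detected genes from their mean over the 5 hearts, in log2 units, for lists with at least 3 detected genes, whose number stands beside the list. The erythroid list lies at 0.71 in heart 7 and -0.40 in heart 9.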

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

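Single hearts far from the others were looked for in 100 values by Dixon's ratio, the gap of the extreme heart divided by the whole range. Of these, 10 passed a critical ratio that chance passes in about 1 in 20 independent values. The values included genes named for their spread, such as Ctr9 and Slc4a1, so this rate does not hold here. The tests of array quality in heart 7, of Xist in heart 9 and of single probe sets were chosen after the results were seen. The second red cell list was written after the erythroid pattern and before its own values were seen, and the test of the erythroid spread without heart 7 was planned before.

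Among detected genes, Myh7 (ratio 0.753), Atp2a2 (0.7101) and Pfkm (0.744) were lowest in heart 6. Among genes near or below background, Pecam1 (0.774) was lowest in heart 7, Nkx2-1 (0.778) was lowest in heart 6, Myog (0.731) lowest in heart 9, and Foxa2 (0.715) and Myf5 (0.830) highest in heart 8. Ctr9 (0.804) and Slc4a1 (0.872) were highest in heart 7. Outside the main measurement, 856 of the probe sets without a single gene name were above background in all 5 hearts.

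Erythroid genes stood high in heart 7, where the 9 detected genes had a median difference of 0.89 log2 units from the other hearts, above all 10000 random lists of similar level (percentile 100, 95% range -0.29 to 0.31). Heart 7 was picked for these same high values, so the percentile restates the pattern. An effect of RNA quality on these transcripts stays open, since random lists match on level only and heart 7 had the highest Gapdh 3' to 5' ratio. More red cell RNA in heart 7 is a candidate explanation. A second list of red cell genes, outside the lists above, had 9 detected genes with a median difference of 0.67. This was also at percentile 100 (95% range -0.41 to 0.32), and 7 of the 9 genes were highest in heart 7. Heart 7 was picked for genes of the same cell type, so this percentile is not independent of the first. It cannot tell more red cell RNA from other changes shared by red cell genes. Among abundant red cell transcripts, Hba-x differed by 0.64, Hbb-bh1 by 0.51 and Hbb-y by 0.03, and Tfrc was lower by 0.46. Without heart 7 the erythroid list's median SD was still at percentile 99.72 of random lists, so the remaining hearts also differed more than such lists. Genes of a list are not independent, so the percentile describes these arrays and does not settle how much of the spread comes from heart 7. The design names no difference between hearts to set beside red cell content.

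Xist was higher in heart 9 than in heart 10, and both hearts had Eif2s3y well above background. RNA from another sample in heart 9 might give this, and would raise all 3 Xist probe sets. Of these, 1 was higher in heart 9 than in heart 10 by over 2 expected SDs, at 1.75 log2 units, and the others differed by 0.66 and 0.05. The weaker probe sets lie near background in both hearts, so the explanation stays open. No biological explanation was tested.

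High variance of a gene may reflect a change in 1 probe set and not in the gene. Of 20 detected genes outside the sex-linked list at an unadjusted p under 0.001 in the variance test, 8 had another probe set above background, and of these only Ctr9 passed after adjustment. Their other probe sets moved by a median of 0.063 of the named one's deviation, with a bootstrap range from -0.13 to 0.57 that leaves the question open. For Ctr9 the ratio was 0.013. Sequence differences under a probe and failed probes were not separated, and no biological explanation was tested.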

How the results depend on the processing

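Each probe set on its own and the background list without Prm1 and Pomc were chosen after seeing the data. No paired analysis was possible because all hearts form 1 group. The sarcomere, cell cycle, glycolysis, fatty acid oxidation, liver and lung calls held under every setting run, and so did the wider erythroid spread (ratio 1.51 to 2.48) and sex-linked spread, which could not be computed without dim genes. No call reversed (40 spread ratios of lists without a call crossed 1), and the deposited scale changed no call. Detected genes numbered 5425 to 7565, and the cause of each change below was not tested. Median r was 0.938 at offset 1 and 0.984 at offset 64 (0.973 to 0.979 leaving hearts out). Variable genes numbered 8 at offset 1, 1 with probe sets averaged, 3 without dim genes, 2 without a robust prior, 2 without a trend, 9 probe sets when each was tested alone, and 3 to 9 leaving hearts out. The low calcium handling spread missed the threshold at offsets 1 (ratio 0.719) and 64 (0.838), with probe sets averaged (0.725), without dim genes (0.712), and without heart 6, 8, 9 or 10 (0.606 to 0.739 over the hearts left out). Transcription factors missed it with probe sets averaged (70.8%), at the 99th percentile (54.2%) and with 3 hearts sufficing (83.3%). Cushion genes passed without _x_at and _s_at probe sets (79.2%), at the 90th percentile (83.3%), with 3 hearts sufficing (87.5%) and without heart 9, not with another heart left out (75.0% to 87.5% over the hearts left out). With 3 hearts sufficing, atrial markers (92.3%), epicardium (100%), hypoxia (92.3%) and, in the lower direction, skeletal muscle (28.6%) also passed. Where the mean level of a named gene was compared between settings, it moved by over 1 SD in 101 comparisons and by less in 723. Signal near background limits weak genes most.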

Other observations

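Gene families named by symbol differed in how often they were detected. The families and the examples named were chosen after the data were examined, and their counts were computed with the deposited scaling only. None of 31 Hox genes, which set position along the body axis, was detected, and 4 exceeded background in some hearts (Hoxa7, Hoxb4, Hoxb9 and Hoxc6). None of 28 olfactory receptors was detected. Of 19 Wnt ligands, 2 were detected, Wnt5a at 6.07 ± 0.30 and Wnt5b at 6.98 ± 0.25, and of 22 genes with an Fgf symbol 4 were, the secreted factors Fgf1 and Fgf9 and the intracellular homologous factors Fgf12 and Fgf13. Of 27 interleukins, Il16 and Il18 were detected, and of 62 genes of potassium channels and their associated proteins 11 were. Complex I of the respiratory chain gave signal for 32 of 33 subunits, the proteasome for 35 of 38 and ribosomal proteins for 40 of 45. Collagen chains (18 of 36, adjusted p = 0.739) and zinc finger proteins (89 of 171, adjusted p = 0.739) lay near the share of all genes.

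The hypothesis that the share of detected genes is the same in every family was tested by two-sided Fisher's exact tests, and 10 of 12 families differed from the remaining genes after adjustment. The families were picked and not drawn at random, so this count holds for them alone and not for gene families in general. The adjusted p was 5.36e-10 for Hox genes, 1.19e-07 for complex I and 0.00112 for Fgf genes.

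The strain history leaves segments of parental strains that could differ between hearts and make neighbouring genes vary together. Among 6386 detected autosomal genes, 13 neighbouring pairs were both in the most variable 5%, against a median of 16 in random orders (95% range 9 to 23), so no excess was seen. The count lies within the chance range and the power to detect such segments was not tested, so the explanation stays open. This test was planned before its result was seen.

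Among the probe sets without a single gene name, 1 had the largest SD, 2.06. Its levels were 4.34, 4.04 and 4.70 in hearts 6, 7 and 8 and 7.96 and 8.24 in hearts 9 and 10. Like Eif2s3y, it was high only in hearts 9 and 10, as were those with the next largest SDs, 1.61 and 1.47. The median deviation of macrophage genes was -0.43 in heart 6 and 0.28 in heart 9, and that of hypoxia response genes was -0.36 in heart 7 and 0.24 in heart 8, with neither list past the spread test (adjusted p = 0.814 and 0.406).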
